A study of Mus musculus with 8 samples.

How the data were processed

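Messenger RNA of CD4+ T cells from the spleen of wild-type mice was sequenced in bulk, in 4 libraries from cells given vehicle and 4 from cells given dimethyl succinate for 3 days. RNA was extracted with TRIzol and made into libraries with an mRNA-seq kit, per the labels' protocols. The submitters' processing notes name HISAT2 2.0.5, an aligner of RNA-seq reads. The counting tool, the annotation, the genome build and whether strand was used in counting were not given in the sources used here. The start or end of 99.17% of the 54495 matched genes equalled that in GENCODE M21, an annotation of the mouse build GRCm38, so coordinates are read as GRCm38.

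The authors deposited 1 table of the whole series with raw counts per gene and library, per the file headers, and 54532 genes were listed, of which 27185 had a count in any library. The same table held FPKM values by the authors, per the file headers. In every library these equalled the count divided by the listed gene length and by a library total that stood in a fixed ratio to the DESeq2 size factor, within 2.18e-10%. The authors also deposited group means, named as a normalised signal here because the file headers give no unit. Their log2 fold changes and p-values for dimethyl succinate against vehicle, which the file headers call DMSO, were deposited beside them with an adjusted p-value. The deposited p-values and adjusted p-values do not share one order: 16462 of 24973 genes had an adjusted p of 1. The gene lengths were deposited as base pairs.

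Differential expression was computed from the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 13981 genes, and libraries were scaled by TMM factors. The quasi-likelihood F test with robust dispersions compared all 8 libraries, 4 against 4, with no covariate, and p-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05, two-sided. Standard errors of log2 fold changes were taken from the F statistic, and intervals cover 95%. CPM values were computed from the counts with TMM-scaled library sizes, and log2 CPM used a prior count of 2. Nothing in the labels states that libraries came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

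Before the data were examined, 46 gene lists were fixed, covering T cell subsets and functions, succinate and mitochondrial metabolism, stress responses and markers of other cell types. Of 1012 symbols in them, 4 were not found, and 44 lists had at least 3 tested members. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 44 lists, with an estimated correlation and with fry as alternatives. The genes named in the text were also fixed then: Ccl1; up to 10 per direction among genes past the threshold; up to 4 members of each list with the smallest unadjusted p; and 20 further genes whatever their values. Genes outside this rule are said to be so where they appear, and some genes within it are not reported here.

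Alternatives fixed before the data were examined were DESeq2 1.42.0, limma-voom, limma-trend on log2(FPKM + 1) and on log2(FPKM + 0.1), other scaling factors, no or a stricter low-count filter, a gene length offset, stricter thresholds, the number in the titles as a block, and each library left out in turn. Library quality weights in limma-voom, the lists without members shared with the activation list, the lists with a length offset, and DESeq2 with its filter tuned at 0.1 were added after the data were seen. Single values were compared by exact two-sided permutation over the 70 splits of 8 libraries, which cannot give a p below 0.0286.

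Total counts ran from 13407295 to 16688854 per library. The replicates of a group differed by more than counting noise, with a lowest chi-square per gene of 2.17 over all pairs where 1 comes from counting alone, so no library was counted as a copy of another. On counts simulated from the real means, library sizes and dispersions of the 13981 genes, the edgeR test recovered 98.8% of genes changed 2-fold, 85.4% of genes changed 1.5-fold and 21.8% of genes changed 1.25-fold, for genes of at least 10 CPM. It called 37 of 68905 unchanged genes over 5 simulations. The simulated counts held no library that stood apart as vehicle replicate 4 does, so these shares need not hold for the real libraries. No sample, gene or column of the table was left out of the analysis before the filter.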

Results

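The series profiled the transcripts of mouse spleen CD4+ T cells, the helper T cells that carry the co-receptor CD4, after 3 days with dimethyl succinate or vehicle. Dimethyl succinate is a cell-permeable ester of succinate, an intermediate of the tricarboxylic acid cycle. The series title places the work in T cell infiltration, production of the chemokine CCL1 and kidney fibrosis after obstruction. The question put to these libraries was which transcripts of CD4+ T cells differ after exposure to the ester. Each group held 4 libraries. Total counts were 14506000 ± 994900 (SD, n = 4) under vehicle and 15792000 ± 866300 under dimethyl succinate (SD, n = 4), an exact permutation p of 0.143.

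Transcripts of CD4+ T cells were abundant in both groups. Cd4 stood at 415 ± 65.5 CPM under vehicle and 471 ± 15.5 under dimethyl succinate (SD, n = 4), and Cd3e, a chain of the T cell receptor complex, at 175 ± 30.1 and 185 ± 12.5. Cd8a, the co-receptor of cytotoxic T cells, stood at 0.868 ± 0.163 and 1.08 ± 0.214 CPM. Cd8b1, its partner chain, which lies outside the naming rule and was picked after the data were seen, stood higher, at 4.89 ± 0.124 and 5.68 ± 0.838. Of 7 lists of markers of other cells, B cells, natural killer cells, monocytes and macrophages, dendritic cells, mast cells and basophils, erythroid cells and platelets, and stroma and endothelium, camera called 0 between the groups, with adjusted p from 0.104 to 0.955. Vehicle replicate 4 stood apart from all other libraries. Its mean correlation with the others was 0.981 against 0.989 to 0.991 for the other 7, and 0.252% of its counts were mitochondrially encoded against 1.16% to 1.48%. It is kept in all values below unless a value is given without it. Log2 fold changes of Cd4, Cd3e and Cd8a were 0.18, 0.086 and 0.32, or 0.075, -0.030 and 0.20 without it.

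**Figure D1:**
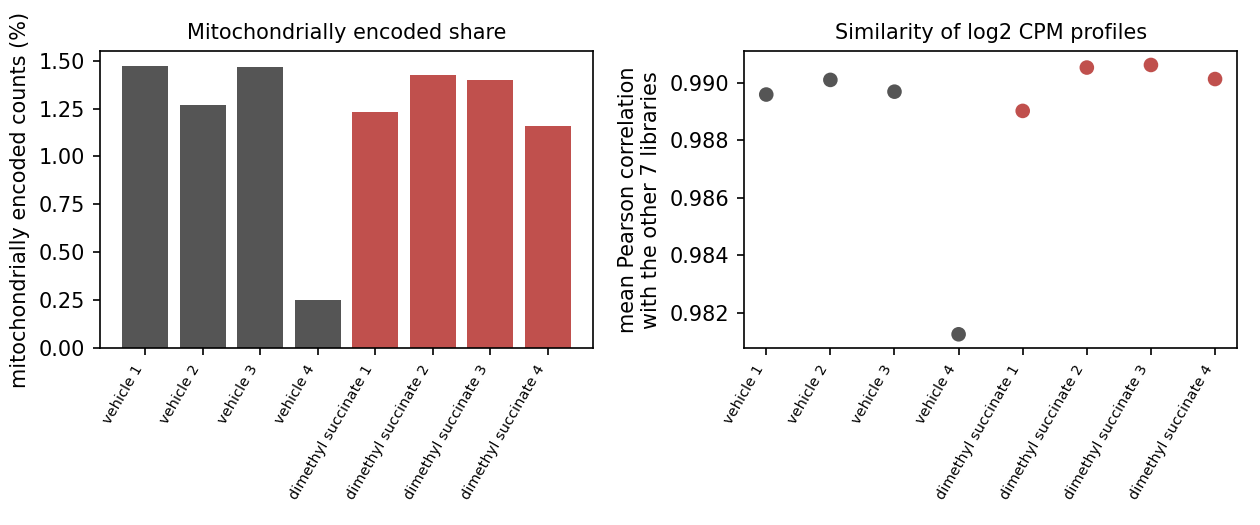
Share of counts from mitochondrially encoded genes in percent (left, bars) and mean Pearson correlation of log2 CPM with the other 7 libraries (right, points), for the 4 vehicle libraries in grey and the 4 dimethyl succinate libraries in red. Vehicle replicate 4 lies at 0.252% and 0.981, below the other 7 libraries on both measures.

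Transcript levels of single genes differed little between the groups. No gene of 13981 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.646. Prag1, a pseudokinase picked after its value was seen, had the smallest p, with 15.8 ± 0.582 CPM under vehicle and 21.6 ± 1.07 under dimethyl succinate (SD, n = 4), a log2 fold change of 0.45 ± 0.086 (SE). Of 8915 genes with a mean of at least 10 CPM, 0 had a log2 fold change of 1 or more in size, and for 8872 the 95% interval excluded a 2-fold change in either direction. At an unadjusted p below 0.05 there were 805 genes, 410 higher and 395 lower under dimethyl succinate, where 699 come by chance. DESeq2 called 0 genes and had 867 at an unadjusted p below 0.05, and limma-voom called 0 and had 841. The 4 libraries of each group did not overlap for 674 genes, 4.82% of those tested, where chance gives 2.86%. The count of 0 depended on vehicle replicate 4: without it the same test called 28 genes, 18 higher and 10 lower. With that library kept, 6 genes were called with no low-count filter and 1 with the number in the titles as a block. The 1 gene called with the block, CT010467.1, is annotated as ribosomal RNA and was picked after its value was seen.

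**Figure D2:**
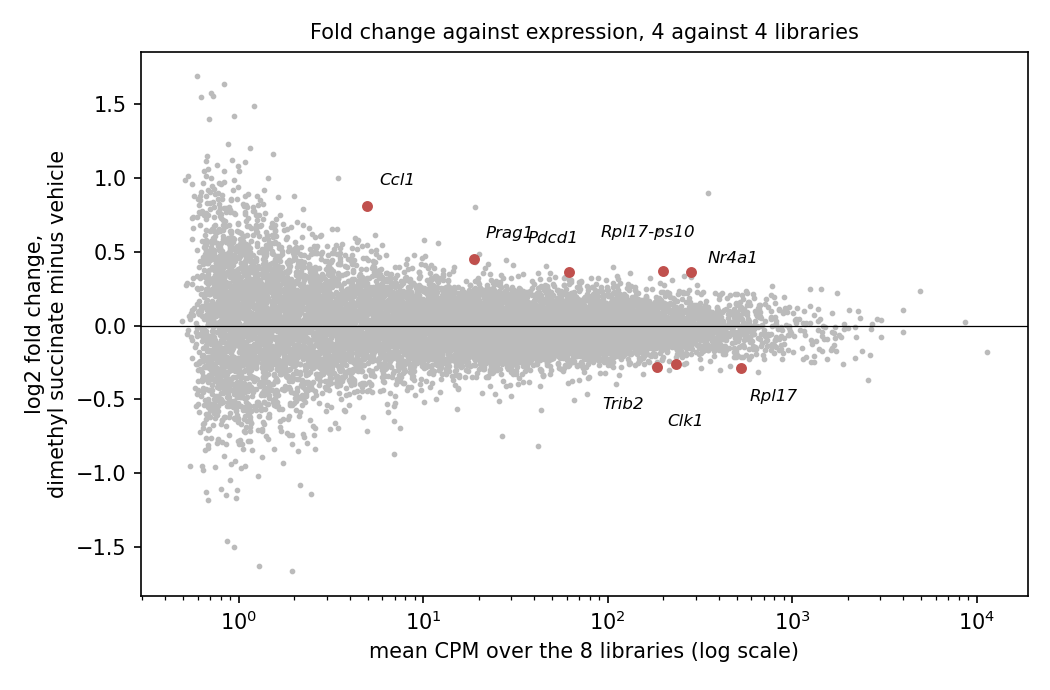
Log2 fold change of dimethyl succinate over vehicle against mean CPM over the 8 libraries (log scale), each point 1 of 13981 genes tested, with named genes in red. Ccl1 lies at 0.81 and Prag1 at 0.45, and no gene passed an adjusted p of 0.05.

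Of the genes called without vehicle replicate 4, those named here were picked after their values were seen, except that the naming rule also takes in Ccl3, Pdcd1, Nr4a3, Pdgfb and Nkg7. The higher ones included Ccl3, a chemokine that recruits monocytes and T cells, at a log2 fold change of 0.44 ± 0.062 (SE), Pdcd1, which encodes the inhibitory receptor PD-1, at 0.41 ± 0.072, Nr4a3, an early response transcription factor, at 0.24 ± 0.046, and Pdgfb, a growth factor for mesenchymal cells, at 0.54 ± 0.099. Nkg7, a cytotoxic granule protein, was at 0.44 ± 0.075 and Spry1, an inhibitor of receptor signalling, at 0.40 ± 0.071. Gm26772, annotated as a long intergenic noncoding RNA, had the largest change and the largest SE of the 28, at 2.82 ± 0.579. The lower ones included Trib2, a pseudokinase, at -0.25 ± 0.047, and Clk1, a kinase of splicing factors, at -0.25 ± 0.049. Rpl17, a ribosomal protein gene, fell by 0.35 on the log2 scale while its processed pseudogene Rpl17-ps10 rose by 0.33, with adjusted p of 0.00198 and 0.00767 in edgeR's quasi-likelihood test. The pseudogene shares 75.9% of its 50-base windows with Rpl17 transcripts, so the counts of both are uncertain. Spry1 shares 24.4% of its exon bases with Gm42922 on the opposite strand, and counting by strand was not stated.

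Ccl1, which encodes the chemokine named in the series title, was higher under dimethyl succinate in all 4 libraries than in any vehicle library. It stood at 3.60 ± 0.747 CPM under vehicle and 6.32 ± 1.6 under dimethyl succinate (SD, n = 4). This rested on 37 to 61 counts per vehicle library and 80 to 134 per dimethyl succinate library. The log2 fold change was 0.81 ± 0.209 (SE), with a 95% interval of 0.36 to 1.26. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 can give. In edgeR's quasi-likelihood test the adjusted p was 0.709 over all genes and 0.0248 adjusted over the list alone, the list being the chemokine ligands. The study may have picked CCL1 from these libraries, so the value over the list alone is not independent evidence of its direction. The gene model of Ccl1 (ENSMUSG00000020702) lies on the minus strand of chromosome 11 from 82176657 to 82305690 (GRCm38), spans 129034 bases and has 2369 exon bases, none shared with another annotated gene.

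Chemokine ligands, the secreted attractants of immune cells, were higher as a list. Of 18 tested, 13 had a log2 fold change above 0, 4 were higher at an unadjusted p below 0.05 and 0 were lower, with a median of 0.175. Over all genes 0 passed, and 3 passed adjusted over the list alone: Ccl1, Ccl22 and Ccl5. Ccl22, a ligand of the receptor CCR4, stood at 36.6 ± 3.37 CPM under vehicle and 46.8 ± 5.02 under dimethyl succinate, and Ccl5 at 9.73 ± 2.58 and 14.3 ± 0.947 (SD, n = 4). Ccl3 stood at 146 ± 45.3 and 229 ± 21.2. Camera gave the list an adjusted p of 0.000615 at the preset correlation, and the adjusted p was 0.451 with an estimated correlation. The exact permutation p of the list means was 0.0571. Ccr8, which encodes the receptor for CCL1, stood at 133 ± 28.6 and 136 ± 12.7 CPM, a log2 fold change of 0.032 ± 0.142 (SE) that was -0.11 without vehicle replicate 4. The list of chemokine and homing receptors was not called, with an adjusted p of 0.407.

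**Figure D3:**
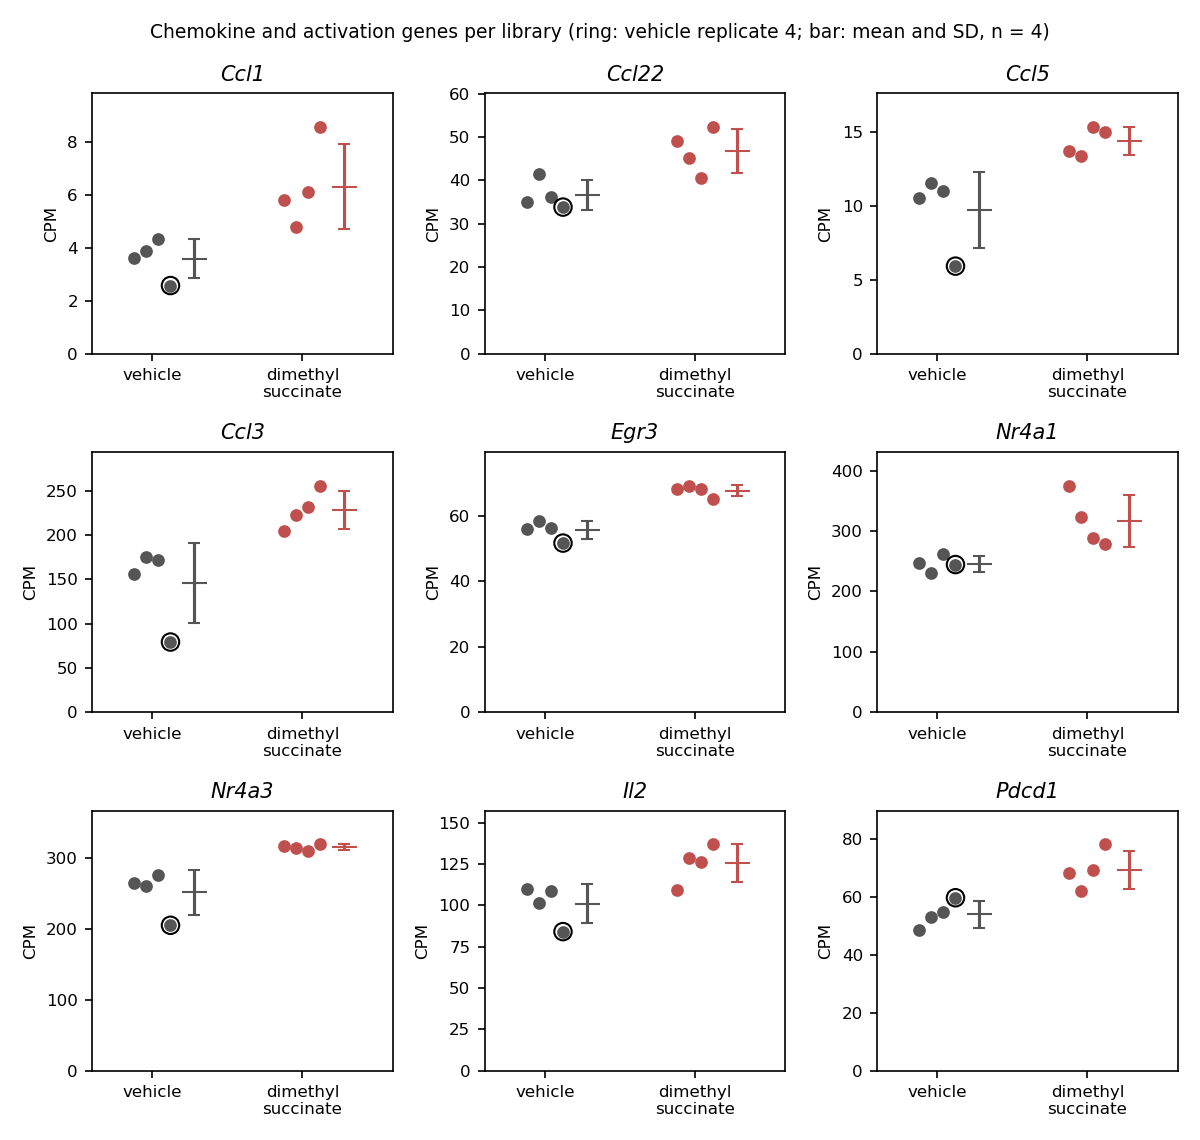
CPM of 9 genes in each of the 4 vehicle libraries (grey) and 4 dimethyl succinate libraries (red), with the group mean and SD beside the points and vehicle replicate 4 ringed. Ccl1 runs from 2.57 to 4.34 CPM under vehicle and from 4.77 to 8.56 under dimethyl succinate, and vehicle replicate 4 is the lowest library for Ccl1, Ccl22, Ccl5, Ccl3, Egr3, Nr4a3 and Il2.

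T cell activation genes, those induced when the T cell receptor is engaged, were higher as a list under dimethyl succinate by a small amount. Of 29 tested, 23 had a log2 fold change above 0, 10 were higher at an unadjusted p below 0.05, and the median was 0.12. The 1 member lower at that p was Cd69, an early activation antigen picked after its value was seen, at -0.12 ± 0.056 (SE). Over all genes 0 passed, and 4 passed adjusted over the list alone: Egr3, Nr4a1, Nr4a3 and Il2. Egr3, an early growth response transcription factor, stood at 55.7 ± 2.84 CPM under vehicle and 67.8 ± 1.71 under dimethyl succinate (SD, n = 4), a log2 fold change of 0.28 ± 0.065 (SE). Nr4a1 and Nr4a3, orphan nuclear receptors induced by receptor signalling, had log2 fold changes of 0.36 ± 0.088 and 0.33 ± 0.083. Il2, a growth factor of T cells, was at 101 ± 11.9 and 125 ± 11.5 CPM. Camera gave an adjusted p of 5.99e-07 at the preset correlation, the adjusted p was 0.0561 with an estimated correlation, and fry gave 0.0356. The estimate was 0.0104, near the preset 0.01, so its size does not account for the higher p. The list kept its call at the preset correlation with each library left out in turn, and without vehicle replicate 4 the camera adjusted p was 7.91e-10, and it was 0.0889 with an estimated correlation.

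Inhibitory receptors and exhaustion genes, which restrain activated T cells, were higher as a list as well, and 4 of their tested members are also on the activation list. In dimethyl succinate replicate 3 the mean log2 CPM deviation of the list was -0.0588, below vehicle replicates 2 (-0.0357) and 3 (-0.0139). The other dimethyl succinate libraries lay above every vehicle library, and the exact permutation p of the list means was 0.0857. Of 18 tested, 17 lay above 0 and 5 were higher at an unadjusted p below 0.05, with a median of 0.12. Adjusted over the list alone, 3 passed, Pdcd1, Nr4a1 and Nr4a3, and 0 passed over all genes. Pdcd1 stood at 54.0 ± 4.62 CPM under vehicle and 69.5 ± 6.61 under dimethyl succinate (SD, n = 4), a log2 fold change of 0.36 ± 0.086 (SE). Camera gave an adjusted p of 3.72e-05, which was 0.0448 without the 4 shared members, the adjusted p was 0.0561 with an estimated correlation, and fry gave 0.0395. The estimate for this list was 0.00531, below the preset 0.01, so its size does not account for the higher p. Follicular helper T cell genes were also higher, with a camera adjusted p of 0.00137, which was 0.602 with an estimated correlation and 0.169 without vehicle replicate 4. The exact permutation p of that list's means was 0.0286, or 0.419 adjusted over the 44 lists. Of 17 members 15 lay above 0, with a median of 0.11, or 0.065 without vehicle replicate 4. Adjusted over the list alone Pdcd1 and Angptl2 passed, and Cxcr5 and Bcl6, the receptor and transcription factor that mark these cells, had log2 fold changes of 0.33 ± 0.128 and 0.32 ± 0.151 (SE).

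Genes of T helper 1 cells, regulatory T cells and the NF-kB pathway were higher as lists at the preset correlation. Of 20 T helper 1 genes, 13 lay above 0, 5 were higher and 1 lower at an unadjusted p below 0.05, with a median of 0.18, or 0.075 without vehicle replicate 4, and a camera adjusted p of 0.00763. That list kept its call with each library left out, but not with an estimated correlation, where the adjusted p was 0.16. The estimate for T helper 1 genes was -0.000296, below the preset 0.01, so its size does not account for the higher p. Ifng, their signature cytokine, stood at 182 ± 44.3 and 221 ± 41.3 CPM (SD, n = 4), a log2 fold change of 0.28 that ran from 0.17 without dimethyl succinate replicate 4 to 0.45 without vehicle replicate 4. Ifng shares 25.9% of its exon bases with Gm49751 on the same strand. Tbx21, their master transcription factor, stood at 108 ± 3.63 and 112 ± 7.02 CPM, and Irf1 had a log2 fold change of -0.21 ± 0.068 (SE). Of 25 regulatory T cell genes, 21 lay above 0, with a median of 0.052 and a camera adjusted p of 0.0168, or 0.0448 without 3 members shared with the activation list. The adjusted p was 0.5 with an estimated correlation, 0.0856 without vehicle replicate 4 and 0.0584 without dimethyl succinate replicate 1. Foxp3, their lineage factor, stood at 64.4 ± 18.4 and 79.3 ± 4.47 CPM, a log2 fold change of 0.30 that was 0.11 without vehicle replicate 4, with 18.6% of its exon bases shared with Flicr on the same strand. Of 25 NF-kB target genes, 18 lay above 0, with a median of 0.042, or 0.11 without vehicle replicate 4, a camera adjusted p of 0.0407 and members moving both ways. The adjusted p was 0.602 with an estimated correlation, 0.181 without 3 members shared with the activation list, and 0.0533 to 0.192 without vehicle replicate 1, 2 or 3 or dimethyl succinate replicate 1, 2 or 4. Traf1 was at 0.18 ± 0.057 and Tnfaip3, a feedback inhibitor of the pathway, at -0.13 ± 0.054. Adjusted over the list alone no member of the 3 lists passed. Exact permutation p of the list means was 0.0571 for T helper 1, 0.114 for regulatory T cell and 0.0286 for NF-kB genes. Adjusted over the 44 lists the last was 0.419.

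Lists of cell cycle entry, stress response, ribosome and respiratory chain genes were lower under dimethyl succinate by camera at the preset correlation, and none kept its call with an estimated one. In dimethyl succinate replicate 4 the mean log2 deviation was instead highest of the 8 libraries for G1/S (0.129) and respiratory chain genes (0.109). For ribosomal protein genes it was 0.0876, above every vehicle library but replicate 2 (0.099). It was -0.0732 for ATF4 genes and -0.0252 for unfolded protein response genes. Exact permutation p of the list means ran from 0.114 to 0.543 over the 5 lists. Of 30 genes of the G1/S phase, 6 lay above 0 and 3 were lower at an unadjusted p below 0.05, with a median of -0.048 and an adjusted p of 0.0153. That p was 0.81 with an estimated correlation and 0.0516 to 0.145 without vehicle replicate 2 or dimethyl succinate replicate 1 or 2. E2f1, a transcription factor of S phase entry, had a log2 fold change of -0.24 ± 0.092 (SE) and Pola1, a subunit of DNA polymerase alpha, -0.21 ± 0.087. Of 31 genes of the ATF4 and integrated stress response, 7 lay above 0, with a median of -0.082, or -0.024 without vehicle replicate 4, and an adjusted p of 0.0156. That p was 0.602 with an estimated correlation, 0.391 without vehicle replicate 4 and 0.0588 without dimethyl succinate replicate 4. Psat1, an enzyme of serine synthesis, was at -0.12 ± 0.054 and Sesn2, a stress-induced inhibitor of mTORC1, at 0.15 ± 0.052. Of 25 unfolded protein response genes, 4 lay above 0, with a median of -0.076, or -0.015 without vehicle replicate 4, and an adjusted p of 0.0407. That p was 0.602 with an estimated correlation and 0.0584 to 0.406 without vehicle replicate 4 or any dimethyl succinate replicate. Pdia3, a protein disulfide isomerase, was at -0.27 ± 0.124, or -0.12 without vehicle replicate 4. Of 53 cytosolic ribosomal protein genes, 19 lay above 0, and of 60 nuclear genes of the respiratory chain and ATP synthase, 16 did, each list with an adjusted p of 0.0449 that a gene length offset moved to 0.159 and 0.161. With an estimated correlation it was 0.857 and 0.919. The ribosomal list had 0.0584 to 0.446 without vehicle replicate 2 or dimethyl succinate replicate 1, 2 or 3, and the respiratory list 0.13 to 0.569 without those or vehicle replicate 4. Their medians were -0.065 and -0.052, or -0.0385 and -0.022 without vehicle replicate 4. Rps6 was at -0.26 ± 0.112, or -0.11 without vehicle replicate 4, and Ndufb5 at -0.20 ± 0.084, and ribosomal protein genes have many pseudogene copies that can share reads.

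**Figure D4:**
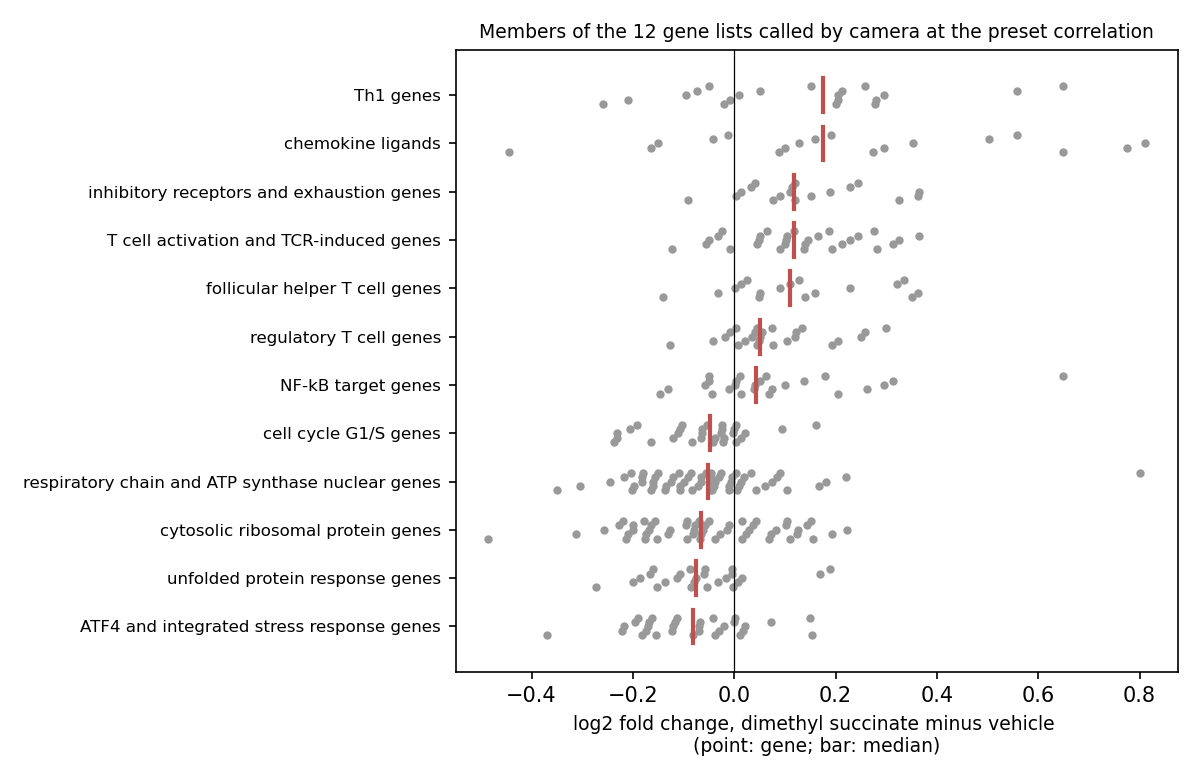
Log2 fold change of dimethyl succinate over vehicle for each tested member (points) and the median (bars) of the 12 lists that camera called at the preset correlation. Medians run from -0.082 for ATF4 and integrated stress response genes to 0.18 for T helper 1 genes, which are -0.024 and 0.075 without vehicle replicate 4, and 0 of the 12 lists had an adjusted p below 0.05 with an estimated correlation.

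The lists nearest to succinate itself were not called. Genes of succinate transport, sensing and formation had a camera adjusted p of 0.7, tricarboxylic acid cycle genes 0.763, HIF-1 target genes 0.774, glycolysis genes 0.763 and 2-oxoglutarate-dependent demethylases and hydroxylases 0.706. Their medians were -0.0068, -0.00048, -0.0033, 0.011 and -0.022, or -0.0057, -0.0057, 0.0064, 0.049 and 0.0081 without vehicle replicate 4. Sdha, the catalytic subunit of succinate dehydrogenase, stood at 287 ± 12.4 CPM under vehicle and 286.9 ± 6.87 under dimethyl succinate (SD, n = 4), Sdhb at 117 ± 15.6 and 109 ± 8.52, and Hif1a at 752 ± 59.6 and 702 ± 51.3. Log2 fold changes of Sdhb and Hif1a were -0.10 and -0.099, or -0.0057 and -0.15 without vehicle replicate 4. Slc16a1, a monocarboxylate transporter, had a log2 fold change of -0.15 ± 0.071 (SE), or -0.079 without vehicle replicate 4. Sucnr1, the succinate receptor, had 2 counts in all 8 libraries together, and no fold was computed. Kdm6b, a histone H3 lysine 27 demethylase, was the only member of these lists to pass adjusted over the list alone, with a log2 fold change of 0.35 ± 0.083 (SE) and an adjusted p of 0.646 over all genes in edgeR's quasi-likelihood test.

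Other lists fixed before the data were examined were not called, among them T helper 2 genes with a camera adjusted p of 0.58, T helper 17 genes with 0.224, naive and quiescence genes with 0.923, cytotoxic effector genes with 0.0939, NRF2 target genes with 0.161, type I interferon response genes with 0.923 and fibrosis-associated secreted and matrix genes with 0.7. Gata3, the T helper 2 lineage factor, stood at 162 ± 23.2 and 155 ± 3.84 CPM (SD, n = 4), Il4 at 11.3 ± 2.42 and 10.4 ± 0.61, Il13 at 17.5 ± 3.94 and 21.8 ± 0.995, Il10 at 104 ± 4.43 and 120 ± 16.4, and Il17a at 6.76 ± 1.33 and 8.34 ± 0.175. Log2 fold changes of Gata3, Il4 and Il13 were -0.060, -0.12 and 0.31, or -0.16, -0.22 and 0.17 without vehicle replicate 4, and that of Il10 was 0.20, or 0.12 without dimethyl succinate replicate 4. In the fibrosis list the median was -0.10, or -0.059 without vehicle replicate 4, while camera's direction was up. Fry's mixed test, which counts changes in both directions, gave that list an adjusted p of 0.00444. Adjusted over the list alone 3 members passed. Lif, a cytokine of the interleukin-6 family, was at -0.21 ± 0.053 (SE), Pdgfb at 0.43 ± 0.118 and Lgals3, which encodes galectin-3, at 0.28 ± 0.082. Oasl2 was the only interferon response gene to pass adjusted over the list alone, with 8.14 ± 0.707 and 12.1 ± 1.93 CPM.

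Other splits of the 8 libraries into 4 and 4 called up to 13 lists, so the count of 12 is within what unrelated groupings give, while no other split gave the activation list a camera p as small. The exact permutation p of that list's mean was 0.0286, or 0.419 adjusted over the 44 lists.

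The authors' deposited table gave 4 genes at an adjusted p below 0.05: Trib2 at a log2 fold change of -0.29, Clk1 at -0.26, Prag1 at 0.45 and Rpl17-ps10 at 0.37. These lie outside the naming rule and were picked after their values were seen. The authors' deposited table gave Ccl1 a log2 fold change of 0.81, a p of 0.000616 and an adjusted p of 1. In edgeR's quasi-likelihood test the 4 genes had log2 fold changes of -0.28, -0.26, 0.45 and 0.37, each with an adjusted p of 0.646. Without vehicle replicate 4 all 4 were among the 28 genes called.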

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

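Tests chosen only after the result was seen were those of the depth of vehicle replicate 4, of a pseudogene sharing reads, of vehicle replicate 4 alone, of fewer resting cells and of the number of genes called by splits of the 8 libraries. Over 262 groups of 4 libraries 20 held a library far from the others, where chance gives about 1 in 20, and 15 of the 20 were vehicle replicate 4.

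Vehicle replicate 4 was low in its mean correlation with the other libraries, at 0.9812 against 0.9896 to 0.9901, and in its mitochondrially encoded share, at 0.2515% against 1.272% to 1.475%. It was low in CPM for Gata3 at 127, Foxp3 at 37.08, Ccr8 at 90.44, Hif1a at 663.7, Cd4 at 316.8, Cd8a at 0.6261, Nfatc1 at 199.9, Rpl17 at 512.6 and Hspa1b at 7.096. Nfatc1 and Rpl17 lie outside the naming rule and were picked after their values were seen. It was high for Traf1 at 254 and Gadd45a at 10.5. Its mean deviation over the naive and quiescence genes was -0.128 and over the mitochondrially encoded genes -2.17. Vehicle replicate 3 was high for Lyz2 at 0.673 CPM. Dimethyl succinate replicate 1 was high for Sdhb at 121.7 CPM and low over cytotoxic effector genes at 0.0155. Dimethyl succinate replicate 4 was high over the respiratory chain genes at 0.109, and dimethyl succinate replicate 3 was low over the unfolded protein response genes at -0.0376.

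Among vehicle libraries, replicate 4 differed from the mean of the other 3 by more than 1 on the log2 scale for 628 of 13981 genes, 476 of them lower, where no other library set against the rest of its group, this library left out, reached more than 232. Depth does not set it apart, since its total of 14780004 counts lies within the range of the other 7. The gap of 0.00778 in mean correlation was 0.00768 after each library's trend with gene length was removed and 0.00725 without the mitochondrially encoded genes, so neither accounts for it. Transcripts of another cell type stay open: the highest median over the lists of other cells was 0.852, for 3 erythroid and platelet genes. The standard error of their mean was 0.274, and the median is short of the bound of 1 by less than that. RNA quality or a different state of these cells was not tested, and the design names no biological difference within the vehicle group.

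The activation list was higher under dimethyl succinate. Its camera p at the preset correlation was 1.36e-08, and the smallest of the other splits gave 2.50e-06. Only the real split, 1 of 35 and the fewest possible, gave a p as small. The camera adjusted p was 0.0561 with an estimated correlation, although the estimate, 0.0104, lay near the preset 0.01. The list had the smallest p of 44, and its exact permutation p of 0.0286 was 0.419 adjusted over them, so chance is not excluded. Gene length does not account for it, since the median log2 fold change was 0.125 after the length trend was removed. After thinning to the smallest library the median was 0.123. Totals ran only from 13407295 to 16688854 and fold changes were already scaled for depth. Thinning could therefore hardly have moved the median and says little about depth. Vehicle replicate 4 did not carry the higher level of the list, with a camera adjusted p of 7.91e-10 without that library, or 0.0889 with an estimated correlation. Without that library the unadjusted camera p was 1.8e-11, and another split of the 7 libraries, with dimethyl succinate replicate 3 among the vehicle ones, gave 3.04e-10. Fewer resting cells under dimethyl succinate stay open, since naive and quiescence genes outside the list had a camera p of 0.861 and moved both ways. A stronger activated state under dimethyl succinate stays open too, and no test here tells these apart.

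Rpl17 and Rpl17-ps10 went in opposite directions. The summed counts changed by -0.106 on the log2 scale, with an exact permutation p of 0.171, while the log2 ratio of pseudogene to gene changed by 0.661, with an exact permutation p of 0.0286, the smallest possible. Reads of the gene assigned to its pseudogene in different shares per library may explain it, as may a sequence variant of the gene between the cells used, which was not tested. Transcription of the pseudogene itself was not tested, and no biological explanation was tested.

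No split of the 8 libraries into 4 and 4 called a gene, so 35 of 35 gave as many as the real count of 0. The real split had 805 genes at an unadjusted p below 0.05, 3 of 35 splits had as many, and the highest other had 1038, so chance cannot be excluded. For lists called the real count was 12, 5 of 35 splits had as many, and the highest other called 13, so chance cannot be excluded either. Without vehicle replicate 4 the real split of 7 libraries called 28 genes, the highest other called 11, and 1 of 35 gave as many, the fewest possible. Leaving that library out answers to its values, so these splits cannot exclude chance for that count.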

How the results depend on the processing

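Of 1768 values of 82 named genes under alternatives, 1715 kept their direction and side of the threshold, 35 passed it only under the alternative and 18 reversed. Ccl1 stayed higher and short of an adjusted p of 0.05 throughout, with log2 fold changes from 0.53 to 0.92. Called genes numbered 6 with no low-count filter (4 higher, 2 lower; 1595 at an unadjusted p below 0.05), and 4 (2 higher, 2 lower) by DESeq2 with its filter tuned at 0.1. Library quality weights, chosen after seeing the data as was that tuning, gave 40 (28 higher, 12 lower; 1350 unadjusted). With 1 library left out the count ran from 0 to 28, 0 to 18 higher and 0 to 10 lower, with 585 to 1216 genes unadjusted. All of these upper ends came without vehicle replicate 4. Called lists were 0 with an estimated correlation, 2 by fry and 6 to 12 with 1 library left out, the fewest without dimethyl succinate replicate 1 and 7 without replicate 2 of that group.

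The labels do not say whether the shared numbers in the titles pair the samples. Correlations of same-number libraries, after group means were removed, were -0.014, 0.0112, 0.0557 and 0.13. Vehicle replicate 4 weighs on every vehicle deviation, so these values cannot exclude pairing. With the number as a replicate block 1 gene was called, 1 higher, and 2 with a gene length offset as well, 1 higher and 1 lower. The higher one was in both cases CT010467.1, annotated as ribosomal RNA. Sdha, near 0, turned to 0.000192 in limma-voom, 0.003229 with upper-quartile factors, 0.01476 with library totals, 0.00198 with no filter, 0.0009101 with a strict filter, 0.0001963 with the replicate block and 0.01305 with quality weights, which also turned Ccr8 to -0.1189 and Cd3e to -0.0133. With 1 library left out Il4 ran from -0.222 to 0.02257, Ccr8 from -0.1147 to 0.09584, Sdha from -0.02167 to 0.02577 and Cd3e from -0.03032 to 0.1493. The cause was not tested. Of the 12 called lists 11 kept their call without members shared with the activation list, NF-kB targets going to 0.181, and 10 with a length offset, which ended those of ribosomal protein (0.159) and respiratory chain genes (0.161). Genes of few counts limit precision: Ccl1 had at most 134 per library.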

Other observations

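Mitochondrially encoded genes as a list had a median log2 fold change of 0.18 and a camera adjusted p of 0.276 with all 8 libraries. Without vehicle replicate 4 the median was -0.16 and the camera adjusted p 5.94e-05, or 0.719 with an estimated correlation. It was the 1 list of the 8 called without that library that was not among the 12.

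Ndufa12, a subunit of respiratory complex I, fell into separate levels. It stood at 33.7 and 34.3 CPM in dimethyl succinate replicates 3 and 4 and between 11.9 and 15.2 CPM in the other 6 libraries, so its log2 fold change of 0.80 ± 0.292 (SE) rests on those libraries. CT010467.1, annotated as ribosomal RNA and picked after its values were seen, stood at 245 ± 99.3 CPM under vehicle and 456 ± 79.4 under dimethyl succinate (SD, n = 4). It was the 1 gene called with the replicate block.

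The adjusted p-values in the authors' deposited table could be rebuilt. DESeq2 with its filter tuned at 0.1, with genes it left unadjusted shown as 1, came within 1e-04 of the deposited value for 24973 of 24973 genes. It adjusted 8511 genes and left 16462, those with a mean scaled count below 184.6. Ccl1 has a mean of 74.4 and is among those left unadjusted, so the adjusted p of 1 in the authors' deposited table does not come from adjusting its p. With the filter tuned at 0.05 the smallest adjusted p was 0.0733, and the 4 genes called in the authors' deposited table then passed no threshold of 0.05.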
